A study of Mus musculus with 12 samples.

How the data were processed

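Gene expression was measured by RNA sequencing in 12 samples of NIH-3T3, an immortalised mouse embryonic fibroblast line. There were 4 groups of 3 samples: PBS (Con), recombinant stanniocalcin-1 at 100 ng/mL (STC1), TGF-β1 at 10 ng/mL (TGFb1), and both proteins together (TS), each for 24 h. The series text states that the 3 samples of a group were biological replicates, and the labels give no batch, date or lane. Per the labels' protocols, RNA was extracted with TRIzol, its integrity was assessed on a Bioanalyzer, and libraries were made from poly-A RNA with the MGIEasy kit. The build GRCm39 is named in the submitters' processing notes. The aligner and the counting program were not given in the sources used here, and neither was whether strand was used.

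The authors deposited a table of expected counts (estimated counts that need not be whole) for 16300 genes, not scaled between samples. That unit was read from the values, since the columns have unequal sums between 16867600 and 18521800 and between 88.5% and 89.1% of the values of a library were whole within 1e-06. How the fractional values arose was not given in the sources used here. Genes with near-identical copies or processed pseudogenes, such as ribosomal protein genes, Gapdh, Ldha, Pgk1, Tpi1 and Mif, are uncertain where the counting could split their reads. Gene numbers were matched to symbols in a RefSeq table of the earlier build GRCm38 for 16177 genes, and the 123 without a match held at most 0.123% of a library's counts. No positions are given, because the reference used here and the authors' build differ. Genes encoded by mitochondrial DNA were not analysed here.

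Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr, which left 11763, and libraries were scaled by TMM. All 12 libraries were fitted together with 1 mean per group, which leaves 8 residual degrees of freedom, and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust moderation. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over all tested genes within a comparison. A gene was called at an adjusted p under 0.05, and "rose" and "fell" are used of called genes. The 6 comparisons were STC1 with Con, TGFb1 with Con, TS with TGFb1, TS with Con, TS with STC1, and the interaction, which is the STC-1 effect with TGF-β1 present minus that without it. Fold changes are on the log2 scale with their standard errors (SE), and levels are CPM, counts relative to the TMM-scaled library size, with the SD over 3 libraries. The median biological coefficient of variation was 2.22%, and genes above a log2 CPM of 5, of which there were 6158, had a median SE of about 0.0395 for TGFb1 against Con. A correlation across genes treats genes as points, and genes are not independent replicates.

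Of 30 gene lists, 26 had at least 5 tested members and were tested with camera of limma 3.58.1 on voom values, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the 26 lists within a comparison. The others were macrophage, epithelial and endothelial markers, given as levels, and the mitochondrial list. In each of the 6 comparisons the median, mean and test of the called lists had the same sign. The comparisons, tests, lists and most alternative settings were fixed before the data were examined. So was the rule for named genes: the 8 largest rises and 8 largest falls among called genes without overlap of the groups and with at least 50 mean counts in the higher group (3 each way for TS with Con, TS with STC1 and the interaction), or the 5 smallest p each way where none passed. To these were added up to 4 members with the smallest p of each list described, and Stc1, Tgfb1, Acta2, Col1a1, Col1a2, Col3a1, Fn1, Ccn2 and Smad7, and 1 further gene that is not reported here. Predicted genes and clone names were left out.

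The steps were tested on simulated data. For a simulated TGFb1 with Con comparison over 11706 genes, the test recovered 42.9% of genes changed by 1.1-fold, 79.2% at 1.2-fold, 82% at 1.5-fold and 90% at 2-fold, and 8 of 153 calls were false. This simulation drew genes independently, without variation shared between genes or differences between cultures. Its rates therefore need not hold for the real libraries. Replicates were compared by a chi-square test of their counts. Every pair within a group differed by more than sampling noise, with a chi-square per degree of freedom between 1.45 and 2.41, so none was counted as a duplicate. This check cannot tell separately grown cultures from parts of 1 culture. The p-values set a difference against the spread between these libraries, a median coefficient of variation of 2.22%. They do not measure variation that these libraries do not hold.

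The alternative settings were DESeq2 1.42.0, library sizes without TMM, no low count filter, a mean of at least 50 counts, only the compared groups in the fit, the replicate number as a block, a minimum log2 fold change of 1, an estimated inter-gene correlation, and each library left out in turn. Added after the data were seen were an offset for the trend of each library with transcript length and GC content (splines with 4 degrees of freedom, lengths and GC from GENCODE mouse release 21, fitted above a log2 CPM of 3) and the same genes without it. Length and GC values existed for 97.5% of tested genes. For gene lists, camera with the offset ran on log2 CPM minus the offset, without the precision weights of voom. The lists were not run on such unweighted values without the offset. A list call lost or gained with the offset may therefore come from either change. Simulated unchanged groups that share the same libraries were drawn 20 times for each correlation between comparisons. Figures were drawn with matplotlib 3.10.9.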

Results

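The series concerns stanniocalcin-1, a secreted glycoprotein hormone, in relation to scar formation, the PI3K/AKT pathway and immune genes. NIH-3T3 fibroblasts received PBS, stanniocalcin-1, TGF-β1 (a cytokine that in textbook accounts drives fibroblasts to make matrix and contractile proteins) or both for 24 h, with 3 libraries per group. The libraries held between 16867600 and 18521800 expected counts. The first principal component of 6154 genes with a mean log2 CPM above 5 held 27.0% of the variance and the second 12.4%. Elsewhere the 6158 genes above that level by edgeR's own average are called abundant. Con libraries lay between -4.86 and -2.02 on the first, STC1 libraries between -1.19 and 0.57, TGFb1 libraries between 1.19 and 2.001, and TS libraries between 1.36 and 2.44.

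Stc1 and Tgfb1, the genes of the added proteins, were called in none of the 6 comparisons by the edgeR test, the smallest adjusted p being 0.199 for Tgfb1 in TS against Con. Stc1 stood at 10.53 ± 0.639 CPM (SD, n = 3) in Con and 10.8 ± 1.52 in STC1 libraries. Tgfb1 stood at 21.4 ± 2.10 CPM in Con and 21.02 ± 1.23 in TGFb1 libraries. Both were added as protein, so these levels do not check the labels. Markers of other cell types were low in all groups. Macrophage markers summed to 9.32 ± 0.867 CPM in Con and 9.74 ± 0.0622 in TGFb1 libraries, mostly Cd14 (5.04 CPM over all libraries) and Cd68 (3.498 CPM). Epithelial markers summed to at most 1.03 CPM and endothelial markers to at most 4.22 CPM in a group. Adipocyte markers, mostly Lpl at 29.4 CPM, summed to between 44.9 and 47.5 CPM.

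**Figure D1:**
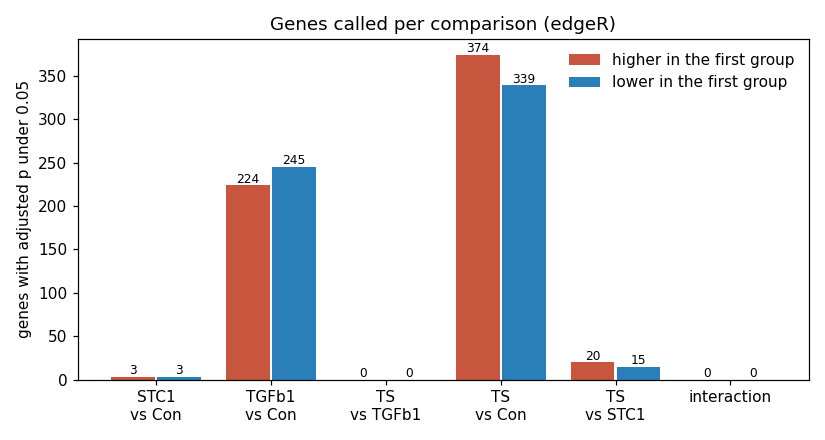
Number of genes with an adjusted p under 0.05 in edgeR (vertical axis) for each of the 6 comparisons (horizontal axis), with red bars for genes higher and blue bars for genes lower in the first group named, or above and below 0 for the interaction. The bars reach 224 and 245 genes for TGFb1 with Con and 374 and 339 for TS with Con, and stand at 0 for TS with TGFb1 and for the interaction.

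The difference between TGFb1 and Con libraries was small in fold and spread over many genes. It cannot be told apart from variation between libraries that needs no treatment. Genes called from these 2 groups alone moved in their called direction by 0.17 on average. They moved by 0.096 from Con to STC1 and by 0.048 from STC1 to TS. Acta2, the smooth muscle actin of myofibroblasts, fell from 390.8 ± 4.36 to 349.9 ± 18.1 CPM (log2 fold change -0.16, SE 0.0285, adjusted p = 0.000286). Genes for the matrix proteins collagen I, collagen III and fibronectin fell too: Col1a2 by -0.15 (adjusted p = 0.00184), Col3a1 by -0.28 (adjusted p = 0.0274) and Fn1 by -0.12 (adjusted p = 0.00429). Col1a1 at -0.17 (adjusted p = 0.199), Ccn2, which encodes connective tissue growth factor, at 0.054 (adjusted p = 0.54) and the feedback inhibitor Smad7 at 0.14 (adjusted p = 0.482) did not pass. In all, 224 genes rose and 245 fell, 469 of 11763, with a median fold of 1.103 among them. At an unadjusted p under 0.05 there were 2083 genes, against 588 expected by chance.

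Among the genes picked by size, the largest rise was in Lif, a cytokine of the interleukin-6 family, from 13.4 ± 0.853 to 19.5 ± 1.99 CPM (log2 fold change 0.53, SE 0.0789, adjusted p = 5.71e-06). It was followed by Sema7a, a membrane-anchored semaphorin (0.48), Ptpre, a receptor-type tyrosine phosphatase (0.45), Sertad4 (0.33), the mitochondrial ribosomal protein gene Mrpl34 (0.31), Rgs16, a regulator of G protein signalling (0.30), Tmem208 (0.29) and Snupn (0.28), with adjusted p between 0.00571 for Tmem208 and 0.0402 for Snupn. The largest fall was in Maf, a transcription factor, from 4.88 ± 0.130 to 3.30 ± 0.383 CPM (log2 fold change -0.56, SE 0.14, adjusted p = 0.0112). It was followed by the aldehyde oxidase gene Aox3 (-0.51), the small proteoglycan gene Aspn (-0.47), the aminopeptidase gene Anpep (-0.44), Arvcf (-0.43), the secreted metalloprotease gene Adamts1 (-0.38, SE 0.0313), the phosphatase gene Ppm1k (-0.37) and Bmf, which encodes a pro-apoptotic BH3-only protein (-0.36). Adamts1 had the smallest adjusted p of the comparison, 5.66e-13. A log2 fold change of 1 or more was reached by 2 called genes, Gm3696 (1.13) and Grin3b (-1.76), which were named after their values were seen and are weakly expressed.

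**Figure D2:**
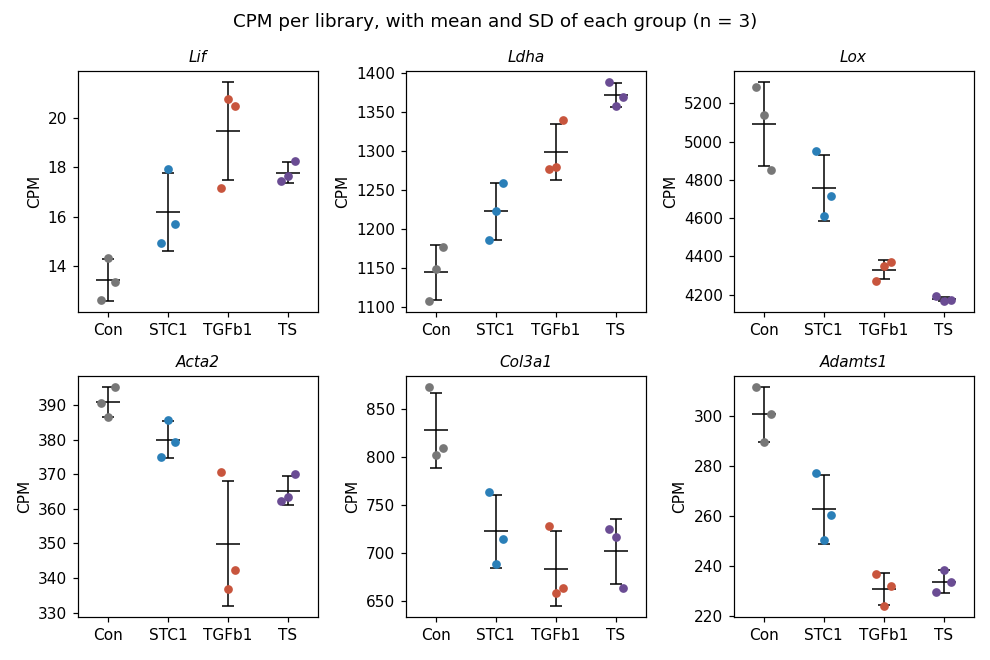
CPM (vertical axes, which do not start at 0) of 6 genes in each library of the Con, STC1, TGFb1 and TS groups (horizontal axes), with points for libraries and black marks for the mean and SD of 3 libraries. Ldha means run from 1145 in Con to 1372 in TS and Lox means from 5093 to 4178, while Adamts1 means run from 300.6 in Con to 230.7 in TGFb1 libraries.

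Matrix genes were lower with TGF-β1 as groups. Of 18 collagen genes 7 fell and none rose (10 fell adjusted over the list alone), among them Col6a2 (-0.15) and Col12a1 (-0.24), with camera's adjusted p = 5.56e-10, and adjusted p = 0.0981 with an estimated correlation. With a trend in transcript length and GC content removed, their median went from -0.10 to -0.061 and the list was still called (adjusted p = 0.000524). Of 27 genes for other matrix proteins 10 fell and 1 rose (14 and 2 adjusted over the list alone; camera's adjusted p = 1.87e-08, and adjusted p = 0.0793 with an estimated correlation). Ogn, a small proteoglycan gene, fell by 0.31 and Fbn1, the fibrillin-1 gene, by 0.14, whereas Spp1, which encodes osteopontin, rose by 0.17. Of 19 collagen processing genes 4 fell and 1 rose (6 and 1 adjusted over the list alone), including Lox, the lysyl oxidase that crosslinks collagen (-0.23, SE 0.0269, adjusted p = 1.71e-08), and camera gave an adjusted p = 0.000663, and adjusted p = 0.0981 with an estimated correlation. Matrix proteases and their inhibitors held 4 falls and 1 rise among 19 (8 and 2 adjusted over the list alone; camera's adjusted p = 0.00032, and adjusted p = 0.0922 with an estimated correlation). Adamts5, an aggrecan-cleaving protease gene, fell by 0.26 and Timp3, a protease inhibitor gene, by 0.12, and the cathepsin gene Ctsl rose by 0.15. Of 20 contractile genes Acta2 fell and Tagln2 rose by 0.096 (3 falls and 1 rise adjusted over the list alone), with camera's adjusted p = 0.000513 downward, and adjusted p = 0.0793 with an estimated correlation.

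Proliferation and glycolysis genes moved the other way. Of 32 cell cycle genes 5 rose and none fell (17 rose adjusted over the list alone), including the replication licensing genes Cdc6 (0.22), Mcm3 (0.13) and Mcm2 (0.10), with camera's adjusted p = 1.01e-10, and adjusted p = 0.0793 with an estimated correlation. Of 27 glycolysis and hypoxia genes 6 rose (9 rose and 1 fell adjusted over the list alone), with Tpi1, Ldha and Pgk1 each at 0.18 and Gapdh at 0.12 (camera's adjusted p = 4.92e-08, and adjusted p = 0.0793 with an estimated correlation). Of 34 ribosomal protein genes 7 rose (21 adjusted over the list alone), with Rpl7 at 0.11 (camera's adjusted p = 1.16e-13, and adjusted p = 0.0793 with an estimated correlation). The median transcript length was 798 nucleotides for the ribosomal protein list and 4987 for collagens, and over 8099 genes the log2 fold change had a Spearman correlation of -0.215 with length and -0.197 with GC content. All 19 cholesterol synthesis genes had a negative fold change, and 6 fell (11 adjusted over the list alone), among them Lss (-0.18), Mvk (-0.17) and Mvd (-0.23), with camera's adjusted p = 1.63e-10, and adjusted p = 0.0793 with an estimated correlation.

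Messenger RNA levels of PI3K/AKT pathway components were slightly lower with TGF-β1. Of 40 components 6 fell and none rose (8 fell and 2 rose adjusted over the list alone; camera's adjusted p = 0.000293, and adjusted p = 0.0922 with an estimated correlation), including the growth factor receptor genes Pdgfra (-0.21) and Pdgfrb (-0.16), the AKT phosphatase gene Phlpp1 (-0.25) and the kinase gene Gsk3b (-0.14). These are transcript levels and do not measure the activity of the pathway. Genes activated by FOXO factors, which AKT inhibits, held 1 fall among 16, in Pdk4 at -0.21, a pyruvate dehydrogenase kinase gene (1 adjusted over the list alone; camera's adjusted p = 0.0174, and adjusted p = 0.118 with an estimated correlation). Complement and MHC class I genes held 3 falls among 11 (5 adjusted over the list alone; camera's adjusted p = 0.00361, and adjusted p = 0.0981 with an estimated correlation). With the length and GC trend removed their median went from -0.099 to -0.064 and the adjusted p was 0.0191. Amino acid synthesis and transport genes driven by ATF4 held 1 rise among 28, in the cystathionase gene Cth at 0.26 (4 rises and 1 fall adjusted over the list alone; camera's adjusted p = 0.00361 upward, and adjusted p = 0.0793 with an estimated correlation). ER chaperone genes held none of 20 by the edgeR test (3 rises and 1 fall adjusted over the list alone), with camera's adjusted p = 0.0376 upward, adjusted p = 0.121 with an estimated correlation, and adjusted p = 0.0887 with a length and GC trend removed. That removal left their median at 0.038, against 0.039 before. The list test with the trend removed also lacked voom's weights, so either change may have ended the call.

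The textbook TGF-β target list did not move as a group. Among its 21 genes 1 rose and Tgfb1i1 (-0.18), Ski (-0.13) and Ltbp2 (-0.16) fell (1 rise and 5 falls adjusted over the list alone), the median log2 fold change was 0.0072 and the mean -0.0078, and camera gave an adjusted p = 0.899. Tgfb1i1 encodes a focal adhesion protein, Ski a repressor of the pathway and Ltbp2 a matrix protein. The camera test also called none of BMP targets (adjusted p = 0.489), cytokines (0.297, with Lif and Mif called), interferon-stimulated genes (0.899), NF-κB targets (0.172), antioxidant genes (0.315), immediate early genes (0.489), integrins (0.878), calcium and phosphate transport (0.172), p53 targets (0.172), YAP targets (0.702) and adipocyte markers (0.247). The count of 469 depended on single libraries: it was 143 without Con replicate 1, 232 without TGFb1 replicate 2 and 205 without TGFb1 replicate 3. Of 59 named called genes, 19 stayed called whichever of the 6 libraries was left out, among them Lif, Adamts1, Acta2, Col1a2, Lox, Adamts5, Ldha and Pdgfra, and none changed sign.

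**Figure D3:**
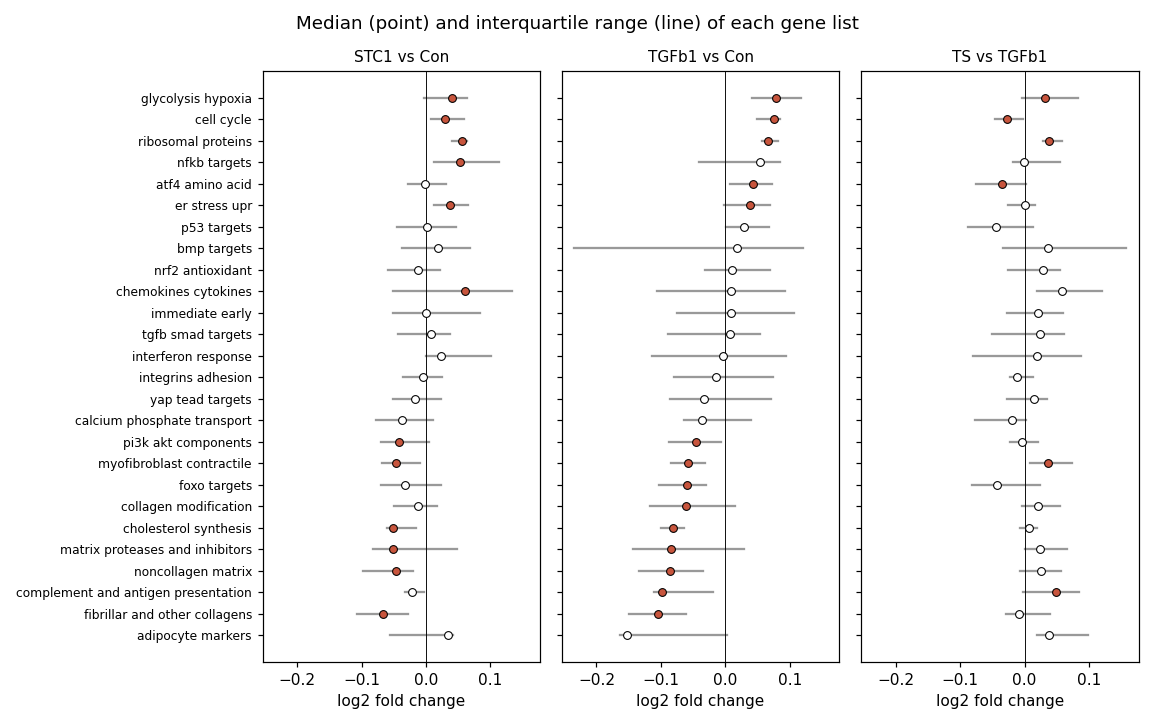
Median log2 fold change (points) and interquartile range (lines) over the tested members of 26 gene lists (rows) in 3 comparisons (panels, horizontal axes in log2 units), with filled points for lists with a camera adjusted p under 0.05. Collagens have a median of -0.066 in STC1 with Con, -0.10 in TGFb1 with Con and -0.0091 in TS with TGFb1, and ribosomal proteins have medians of 0.056, 0.066 and 0.039.

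In STC1 against Con libraries 6 genes were called by the edgeR test. Il6, the gene of the inflammatory cytokine interleukin-6, rose from 6.53 ± 0.850 to 9.13 ± 0.729 CPM (SD, n = 3; log2 fold change 0.48, SE 0.103, adjusted p = 0.0472). Tfrc, the transferrin receptor gene, rose by 0.17 (adjusted p = 0.0154) and Arhgdib by 0.13 (adjusted p = 0.0472). Falls were found in the metalloprotease genes Adamts1 (-0.20, SE 0.0308, adjusted p = 0.000596) and Adamts5 (-0.14, adjusted p = 0.0472) and in Vps26b, a retromer subunit gene (-0.19, adjusted p = 0.041). The scar-related genes were not called, with Acta2 at -0.040, Col1a1 at -0.13, Col1a2 at -0.084, Col3a1 at -0.20, Fn1 at -0.075, Ccn2 at 0.015 and Smad7 at 0.061, the smallest adjusted p being 0.263 for Col1a2. At an unadjusted p under 0.05 there were 1248 genes. DESeq2 called 45, adjusted over the 1501 genes for which it gave an adjusted p, and 4 of these were among the 6. With no low count filter 57 were called, and 52 with the replicate number as a block. The largest 95% limit of any abundant gene was 0.43 in log2 units. Only Adamts1 stayed called in all but 1 of the fits that left out a Con or STC1 library. The count was 0 without Con replicate 1 and 44 without Con replicate 3, 3 without STC1 replicate 2 (Adamts1, Il6 and Mt2, a metallothionein gene named after its value was seen) and 1 without STC1 replicate 3 (Adamts1). Leaving out libraries of the other groups, which enter through the shared spread and filter, gave 14 without TGFb1 replicate 1, 2 (Adamts1 and Tfrc) without TGFb1 replicate 2 or without TS replicate 1, 16 without TS replicate 2 and 31 without TS replicate 3.

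As groups, 6 lists were higher and 6 lower with stanniocalcin-1 by camera, and with an estimated correlation none was called, the lowest adjusted p being 0.173. PI3K/AKT components were lower as a list (adjusted p = 0.00204, and adjusted p = 0.184 with an estimated correlation), but none of the 40 was called by edgeR (3 fell adjusted over the list alone), with Pdgfra at -0.12 and the FOXO factor gene Foxo3 at -0.16. Collagens (median -0.066, adjusted p = 2.01e-06, and adjusted p = 0.211 with an estimated correlation) and other matrix proteins (median -0.047, adjusted p = 8.22e-06, and adjusted p = 0.184 with an estimated correlation) were lower too, with 4 and 6 falls adjusted over the list alone and Col6a2 and the perlecan gene Hspg2 each at -0.11. Contractile genes, matrix proteases and cholesterol synthesis genes were the other lower lists. Their adjusted p were 0.0256, 0.0139 and 0.000243, and with an estimated correlation the adjusted p were 0.211, 0.211 and 0.244. Among immune genes, cytokines were higher (adjusted p = 0.039, with 3 rises adjusted over the list alone), as were NF-κB targets (adjusted p = 0.0175, with 1 rise adjusted over the list alone), both at an adjusted p = 0.184 with an estimated correlation. Mif at 0.12 and Lif at 0.27 were not called, nor was the list of interferon-stimulated genes (adjusted p = 0.44). Ribosomal proteins (median 0.056), ER chaperones, cell cycle genes and glycolysis genes were higher, with adjusted p of 5.21e-15, 0.00204, 0.000132 and 0.00204. With an estimated correlation the adjusted p was 0.173 for the first 2 and 0.184 for the others. The Spearman correlation of the fold change with transcript length was -0.223 and with GC content -0.247, and 7 of the 12 lists were called once that trend was removed. The 5 no longer called were PI3K/AKT components (adjusted p = 0.0908, median from -0.042 to -0.019), collagens (adjusted p = 0.0705, median from -0.066 to -0.032), contractile genes (adjusted p = 0.134, median from -0.046 to -0.044), matrix proteases (adjusted p = 0.103, median from -0.051 to -0.040) and cytokines (adjusted p = 0.222, median from 0.060 to 0.035). The median of contractile genes thus hardly moved with the loss of the call. These list tests also lacked voom's weights, so either change may have ended a call. Calcium and phosphate transport, the textbook field of stanniocalcins, was not called (adjusted p = 0.15), nor were TGF-β targets (0.824).

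Whether stanniocalcin-1 altered the state of TGF-β1-treated cells was addressed by TS against TGFb1, where edgeR called no gene, with 765 at an unadjusted p under 0.05 against 588 by chance. DESeq2 called 1, Rps4x, a ribosomal protein gene, and 4 were called with no low count filter (Mt1, Bnip3, Kif5b and Atp5g2, the last named after its value was seen). With the replicate number as a block 1 was called, Bnip3. None of the scar-related genes was called, with Acta2 at 0.061 (SE 0.0287), Col1a1 at -0.023 (SE 0.0624), Col1a2 at -0.0067 (SE 0.0291), Col3a1 at 0.038 (SE 0.057), Fn1 at 0.0098 (SE 0.0268), Ccn2 at -0.083 (SE 0.0415) and Smad7 at 0.090 (SE 0.0943). Acta2 (0.035 to 0.10), Ccn2 (-0.11 to -0.034) and Col3a1 (0.011 to 0.086) kept their sign in the 6 fits that left out a TGFb1 or TS library. The others changed sign in at least 1 of these fits. Small shifts are therefore not excluded. The smallest p with a positive value belonged to the mitophagy receptor gene Bnip3 (0.20, adjusted p = 0.145), the metallothionein gene Mt1 (0.14), Rps4x (0.10), Ifi27 (0.23) and Lage3 (0.26), and with a negative value to the kinesin gene Kif5b (-0.15, adjusted p = 0.151), the ubiquitin hydrolase gene Uchl3 (-0.23), Atad1 (-0.13), the kinase gene Rock1 (-0.15) and Appbp2 (-0.18). No abundant gene had a 95% limit beyond 0.70 in log2 units. Without TS replicate 3, 6 genes were called, and 1 gene, Bnip3, was called without Con replicate 3, without TGFb1 replicate 3 or without TS replicate 2.

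Small shared shifts of 6 lists were called in TS against TGFb1, none with an estimated correlation. Contractile genes were higher as a group (17 of 20 positive, 1 rise adjusted over the list alone; camera's adjusted p = 0.0111, and adjusted p = 0.255 with an estimated correlation), with Tagln at 0.13 and the focal adhesion gene Zyx at 0.085. Glycolysis genes (5 rises adjusted over the list alone; adjusted p = 9.64e-05) and ribosomal proteins (1 rise adjusted over the list alone; adjusted p = 1.22e-12) were higher too, both at an adjusted p = 0.239 with an estimated correlation. Complement and MHC class I genes were higher as well (C1s1 at 0.089; adjusted p = 0.0183, and adjusted p = 0.255 with an estimated correlation). Cell cycle genes were lower (Mcm6 at -0.086; adjusted p = 0.00699, and adjusted p = 0.291 with an estimated correlation), as were ATF4-driven amino acid genes (adjusted p = 0.0183, and adjusted p = 0.239 with an estimated correlation). Collagens (median -0.0091, mean 0.0051, adjusted p = 0.967) and PI3K/AKT components (adjusted p = 0.714) were not called. Fold changes correlated with transcript length (Spearman -0.165) and GC content (0.263), and once that trend was removed 2 lists were called, ribosomal proteins (median from 0.039 to 0.025) and ATF4-driven genes (-0.035 to -0.045). The adjusted p was then 0.257 for contractile genes (median from 0.037 to 0.019) and for complement genes (0.050 to 0.033). It was 0.0678 for cell cycle genes (median from -0.027 to -0.017) and for glycolysis genes (0.033 to 0.027). The lost calls may also come from the missing voom weights in these list tests.

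Cells given both proteins differed from Con in 713 genes, of which 374 rose and 339 fell. Lif rose by 0.40 (SE 0.0801, adjusted p = 0.000622), Il6 by 0.35 (adjusted p = 0.0339) and the cytokine gene Mif by 0.22. Acta2 (-0.098, adjusted p = 0.0274), Col1a2 (-0.15), Col3a1 (-0.24, adjusted p = 0.0394), Fn1 (-0.11), Lox (-0.29) and Adamts1 (-0.36, adjusted p = 3.51e-12) fell, and Col1a1 at -0.19 did not pass (adjusted p = 0.126). The genes picked by size were Drp2, a dystrophin-related gene (0.65), Sema7a (0.62) and Zpbp (0.54), which rose, and Med12l (-0.62), the linker protein gene Clip4 (-0.60) and the clock-related transcription factor gene Hlf (-0.49), which fell. The count was 276 without Con replicate 1, 421 without Con replicate 2 and 351 without TS replicate 1. Of 28 named called genes 17 stayed called whichever of the 6 libraries was left out, while Drp2 and Col3a1 lost their call in each of these 6 fits.

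Ribosomal protein and glycolysis genes were the lists that stayed called in TS against Con with an estimated correlation, both at an adjusted p = 0.0167. Of 34 ribosomal protein genes 25 rose (31 adjusted over the list alone; camera's adjusted p = 2.61e-31), with Rps14 at 0.16 and Rpl13 at 0.15. Of 27 glycolysis and hypoxia genes 10 rose (12 adjusted over the list alone; camera's adjusted p = 5.65e-13), with Ldha, the lactate dehydrogenase gene, at 0.26 (SE 0.0267, adjusted p = 2.71e-10), Tpi1 at 0.22, Pgk1 at 0.21 and Gapdh at 0.17. The Spearman correlation of the fold change with transcript length was -0.315 here. PI3K/AKT components held 7 falls among 40 (10 falls and 2 rises adjusted over the list alone; camera's adjusted p = 0.000137, and adjusted p = 0.113 with an estimated correlation), including Gsk3b (-0.22), Foxo3 (-0.23) and Pdgfra (-0.17). Genes activated by FOXO factors held 2 falls among 16, Pdk4 (-0.21) and the cell cycle inhibitor gene Cdkn1b (-0.17), with 6 adjusted over the list alone and adjusted p = 0.113 with an estimated correlation. Collagens held 8 falls among 18 (10 adjusted over the list alone) and cholesterol synthesis 6 among 19 (9 adjusted over the list alone), the latter with Mvd at -0.24 and Dhcr7 at -0.23, and with an estimated correlation their adjusted p were 0.128 and 0.113. Of 14 lists called at the preset correlation, 9 were called after the length and GC trend was removed. The 5 no longer called were collagen processing genes (median from -0.066 to -0.053), matrix proteases (-0.042 to -0.040), cytokines (0.090 to 0.061), antioxidant genes (0.050 to 0.039) and calcium and phosphate transport genes (-0.050 to -0.021). Here too the list test lacked voom's weights, which may also have ended a call.

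The effect of TGF-β1 in the presence of stanniocalcin-1, TS against STC1, comprised 20 genes that rose and 15 that fell. Glycolysis led, with 9 of 27 genes called upward (10 adjusted over the list alone; camera's adjusted p = 2.42e-13, and adjusted p = 0.0303 with an estimated correlation), among them Pfkl, a phosphofructokinase gene (0.19), Ldha (0.17), Pgk1 (0.15) and Gapdh (0.13). Lox fell from 4758 ± 173 to 4178 ± 11.9 CPM (log2 fold change -0.19, SE 0.0269, adjusted p = 3.73e-05), and Adamts1 fell by 0.17 and Adamts5 by 0.13. By size the rises were led by the protocadherin gene Pcdhgc5 (0.60), which shares exons with the other genes of its cluster, Plk3, a stress-responsive kinase gene (0.29), and the hypoxia-induced gene Higd1a (0.27), and the falls after Lox by the bicarbonate transporter gene Slc4a7 (-0.18) and the BMP receptor gene Bmpr2 (-0.17). FOXO-activated genes (Cdkn1b at -0.16), collagens and cholesterol synthesis genes were lower as lists, with adjusted p of 0.00337, 0.00337 and 0.000255, and with an estimated correlation adjusted p of 0.147, 0.735 and 0.493. Antioxidant genes (adjusted p = 0.00148) and ribosomal proteins (Rps15 at 0.12; adjusted p = 2.56e-15) were higher, and with an estimated correlation their adjusted p were 0.065 and 0.0652. Without TS replicate 3 only the lists of glycolysis, antioxidant and ribosomal protein genes were called. The count of 35 genes was 2 without TS replicate 1 (Ldha and Lox), 16 without STC1 replicate 1 or replicate 2, 13 without STC1 replicate 3 and 21 without TS replicate 2.

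No gene departed from additivity of the 2 treatments by the edgeR interaction test, with 975 genes at an unadjusted p under 0.05 and 0 called by DESeq2. The smallest p with a positive interaction were those of Adamts1 (0.21, SE 0.0444), Plau, the urokinase gene (0.47, SE 0.102), and the matricellular gene Smoc2 (0.24, SE 0.0542), each at an adjusted p = 0.132, then Rsrp1 (0.23) and Ablim1 (0.35). Those with a negative value were Appbp2 (-0.29), Atad1 (-0.19), the exonuclease gene Exo1 (-0.25), Oxsr1 (-0.18) and Serpina3i (-0.39), which belongs to a cluster of near-identical serpin genes. Acta2 at 0.10, Col1a1 at 0.11 and Col3a1 at 0.24 did not pass. With no low count filter 8 genes were called, namely Adamts1 and Col3a1 (both at an adjusted p = 0.00318), Plau, Smoc2, Rsrp1, Appbp2, Atad1 and Igsf10, the last named after its value was seen. With the replicate number as a block edgeR called 5, namely Col3a1 (adjusted p = 0.000213), Adamts1, Plau, Smoc2 and Igsf10. A single gene was called without Con replicate 1 or without STC1 replicate 3 (Plau) and without Con replicate 2 or without STC1 replicate 1 (Adamts1), and 2 without Con replicate 3 (Gm3696 and Zyx, named after their values were seen).

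Across 11763 genes the effect of stanniocalcin-1 without TGF-β1 and that with it, which share no library, had a Pearson correlation of 0.0287 and a Spearman correlation of -0.0042. With no gene called in TS against TGFb1, no overlap of calls could be counted. The sign of this Pearson correlation was not stable: it was positive without Con replicate 2, STC1 replicate 1 or TGFb1 replicate 3, and negative without any of the 9 others, from -0.194 without STC1 replicate 3 to 0.102 without STC1 replicate 1. These fits also filtered the genes anew, so the 2 changes cannot be told apart. With all libraries it was -0.00997 with no low count filter and -0.0266 at a mean of at least 50 counts. The effect of TGF-β1 without and with stanniocalcin-1 had a Pearson correlation of 0.0523 and a Spearman correlation of 0.180. This Pearson correlation was positive without STC1 replicate 1, TGFb1 replicate 2 or TGFb1 replicate 3, and negative without any of the 9 others, from -0.164 without STC1 replicate 3 to 0.0656. Over abundant genes, a set chosen after the results were seen, the stanniocalcin-1 effects had a Pearson correlation of 0.0129 and the TGF-β1 effects one of 0.337. From group means the latter was 0.339, and no other of 100 combinations of splits matched its size. Fits with a library left out were not run for that set. Between the TGF-β1 effects 10 genes rose in both and 6 fell in both, against 0.381 and 0.312 for independent lists, and no gene moved opposite ways. Of the 469 genes called in TGFb1 against Con, 387, or 82.5%, had the same sign in TS against STC1. Whether stanniocalcin-1 moved TGF-β1-responsive genes back was asked by setting TS against TGFb1 beside TGFb1 against Con. These share the TGFb1 libraries, which gives a correlation of -0.504 for simulated unchanged groups. The observed correlation was -0.598 and the covariance -0.0157, against -0.0067 simulated. Over abundant genes the correlation was -0.235, weaker than the -0.510 simulated for them. The simulation draws genes independently, which makes its range too narrow, and no regrouping of libraries was run for this pair. These values therefore do not decide whether TGF-β1-responsive genes moved back.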

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

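The tests of the length and GC trend and of the estimated correlation in this part were chosen after the results were seen. Lists whose STC-1 effect differed with and without TGF-β1, by camera on the interaction, are given first.

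In the interaction, 9 of 26 lists differed at the preset correlation. Higher were collagens (adjusted p = 0.000485), other matrix proteins (adjusted p = 1.61e-05), collagen processing genes (adjusted p = 0.0371), contractile genes (adjusted p = 0.000485), matrix proteases (adjusted p = 0.00253), complement and MHC class I genes (adjusted p = 0.014) and cholesterol synthesis genes (adjusted p = 0.0045). Lower were cell cycle genes (adjusted p = 1.68e-06) and ER chaperones (adjusted p = 0.014). The medians ran from -0.060 for cell cycle genes to 0.089 for contractile genes, with 26 of 32 and 18 of 20 members on that side, and no member was called over all genes.

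A trend with transcript length and GC content was set against these lists, since the interaction had a Spearman correlation of 0.361 with GC content. The list test with the trend removed also lacked voom's weights, so a call lost or gained may come from either change. After that trend was removed, 5 of the 9 were still called, which argues against it as the whole cause for those 5: cell cycle genes (adjusted p = 6.89e-05, median from -0.060 to -0.051), other matrix proteins (0.00419, 0.077 to 0.046), cholesterol synthesis (0.019, 0.055 to 0.046), contractile genes (0.0364, 0.089 to 0.052) and matrix proteases (0.0367, 0.062 to 0.029), while ATF4-driven amino acid genes, not called before (adjusted p = 0.0571), became called (0.00555, -0.024 to -0.045). No longer called were collagens (median from 0.074 to 0.020, interquartile range from 0.037 to 0.11 before and -0.0080 to 0.052 after) and collagen processing genes (0.029 to 0.0021, ranges 0.0011 to 0.078 and -0.023 to 0.068), whose shift shrank, complement genes, which kept more of it (0.073 to 0.046, ranges 0.014 to 0.13 and -0.0011 to 0.12), and ER chaperones, where it did not shrink (-0.035 to -0.045, ranges -0.068 to -0.0089 and -0.054 to -0.0095), so a smaller shift is not why that call ended, and the cause was not tested. With an estimated correlation 0 of the 9 were called, and the lowest adjusted p was 0.243, so the lists may reflect variation that their members share between replicates. Of 100 regroupings of the 12 libraries, the real one included, 17 gave as many lists, and the highest other gave 13. These regroupings mix libraries of groups that differ, which can add called lists, so they do not isolate the interaction. Chance is thus not excluded, and a biological interaction of the proteins stays open.

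For single genes in the interaction the real count was 0, which each of 100 regroupings reaches whatever the data, so the splits decide nothing about it. The highest other count was 269, in a regrouping that mixes libraries of groups that differ.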

How the results depend on the processing

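The tests with an offset for transcript length and GC content, and those on the same genes without it, were chosen after the results were seen. List tests with the offset also ran without voom's weights. Library depth is similar throughout, and low counts limit mainly weakly expressed genes. For STC1 with Con (6 called genes) DESeq2 called 45, adjusted over 1501 genes against 11763 in edgeR. Numbers of called genes were 13 without TMM, 57 with no low count filter, 13 at a mean of at least 50 counts, 22 with only the compared groups, 14 on genes with length and GC values, 26 with the offset, 0 at a minimum log2 fold change of 1, and 0 to 44 with 1 library left out. TGFb1 with Con (469) gave 2 at that minimum and 143 to 561 with 1 library left out, TS with Con (713) gave 0 and 276 to 722, and TS with STC1 (35) gave 0, 64 with no filter and 2 to 39. TS with TGFb1 (0) gave 1 by DESeq2 (Rps4x), 4 with no filter (Mt1, Bnip3, Kif5b and Atp5g2), 2 with only the compared groups (Rps29 and Entpd4, which has a near-identical copy), 1 with the offset (Bnip3) and 0 to 6 with 1 library left out, and the interaction (0) gave 8 with no filter and 0 to 2. Genes outside the naming rule were named here after their values were seen. Called lists under the estimated correlation were 0, 0, 0, 2, 1 and 0 in the order STC1 with Con, TGFb1 with Con, TS with TGFb1, TS with Con, TS with STC1 and interaction, and with the offset 7 for the first, 2 for TS with TGFb1 and 9 for TS with Con; with 1 library left out they were 9 to 13, 13 to 14, 4 to 7, 10 to 13, 3 to 7 and 7 to 10. The correlation of the stanniocalcin-1 effects (0.0287) was -0.00997 with no filter, -0.0266 at a mean of at least 50 counts and -0.194 to 0.102 with 1 library left out. That of the TGF-β1 effects (0.0523) was 0.195 at that mean and -0.164 to 0.0656, and that of TS with TGFb1 against TGFb1 with Con (-0.598) was -0.511 with no filter, -0.364 at that mean and -0.742 to -0.465. Except for the stricter settings, which remove calls or genes by construction, the cause was not tested. No named called gene changed sign in any of these settings. Uncalled genes near 0 did with 1 library left out: in STC1 with Con, Stc1 ranged from -0.036 to 0.15, Tgfb1 from -0.059 to 0.066 and Ccn2 from -0.026 to 0.049; in TGFb1 with Con, Tgfb1 from -0.10 to 0.023, and was 0.017 with the offset; in TS with TGFb1, Stc1 from -0.15 to 0.027, Col1a1 from -0.076 to 0.017, Col1a2 from -0.039 to 0.014, Fn1 from -0.019 to 0.033 and Smad7 from -0.0094 to 0.21; and in TS with Con, Ccn2 from -0.068 to 0.0071. The replicate number as a block gave 52 genes for STC1 with Con, 1 for TS with TGFb1 (Bnip3) and 5 for the interaction (Adamts1, Smoc2, Col3a1, Igsf10 and Plau), and moved no other count of genes or lists by over 1.5 times. The 18 pairs of libraries with the same number had deviations correlated between -0.0232 and 0.245, 6 of them over 0.1. Their mean was 0.078, and 9 of 12 libraries correlated best with their own number. The mean of -0.039 for pairs of different numbers follows nearly by construction, because deviations cancel within a group, so it adds no evidence. These values lean towards an effect shared by libraries of the same number. The labels state no pairing, so it is neither established nor excluded, and both fits are given. Pseudocount and quantile alternatives were not run, since the values are counts.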

Other observations

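The tests in this part of the length and GC trend, of an axis between libraries, of the precision and of swapped labels were chosen after the results were seen, as were the correlations over abundant genes and the regroupings of 9 libraries. The splits of 6 libraries, the fits without Con replicate 1 and the simulated covariance were planned.

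Of the 6 genes called with stanniocalcin-1, 2 rose and 3 fell with TGF-β1 as well, Tfrc and Arhgdib upward and Adamts1, Adamts5 and Vps26b downward, against 0.0571 and 0.0625 for independent lists. Of 469 genes called with TGF-β1, 145 rose and 150 fell in TS against Con, against 7.12 and 7.06 for independent lists. Both overlaps are between comparisons that share the Con libraries, which raises them, and TS also received TGF-β1. Simulated unchanged groups had an overlap of 0 because groups without an effect yield few calls, so that value measures nothing here. The effects of TGF-β1 without and with stanniocalcin-1, which share no library, had a Pearson correlation of 0.337 over the 6158 abundant genes, 1 of 6 such correlations computed.

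The first pattern is the 469 genes called in TGFb1 against Con at a median fold of 1.103. With the length and GC trend removed 75.8% of them were still called, and a median share of 0.914 of the fold remained, which argues against that trend as the whole cause. Without Con replicate 1 the same genes had a median of 0.892 of their fold, so that library alone does not account for it, although 137 of 469 were still called. An axis of variation between libraries that needs no treatment was tested next. Genes called from Con and TGFb1 libraries alone varied within the STC1 and TS groups by 0.094 of the TGFb1 to Con difference. The 95% interval of 0.0563 to 0.27 is wide with 4 degrees of freedom. It lies under the bound set for such an axis but reaches past the bound set against it, so this test does not decide. In their called direction these genes moved on average by 0.17 from Con to TGFb1, by 0.096 from Con to STC1 and by -0.027 from TGFb1 to TS. All of these use libraries the genes were chosen from. They moved by 0.048 from STC1 to TS, which does not (SD 0.021 and 0.0086, n = 3 each). That move argues against variation unrelated to treatment as the whole cause, for these genes. An effect of TGF-β1 may underlie the calls in part, as a hypothesis, and differences in culture or handling, of the Con group among them, were not tested.

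The second pattern is the flat list of textbook TGF-β targets. Too little precision is argued against, since 100% of the 21 tested members had an upper 95% limit under a doubling, the highest being 0.46 for Itgb3. Swapped labels between Con and TGFb1 libraries are argued against as well: in the 40 genes called from STC1 and TS libraries alone, 0 Con libraries scored at or above the lowest TGFb1 library, with Con at most at -0.050 and TGFb1 at least at 0.018. A transient response that had faded by 24 h, weak activity of the added protein or a line that responds little may each account for it, and none was tested.

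The fold changes of STC1 with Con and TGFb1 with Con had a covariance of 0.00848, above the simulated range of 0.00622 to 0.00738 for unchanged groups that share Con, and a Pearson correlation of 0.417, below its simulated range of 0.460 to 0.535. The bound set in advance was too narrow, because the simulation draws genes independently: of the 840 regroupings of the 9 libraries, each of which shares 1 group, 353 gave a covariance as high as the 0.00807 computed from group means (highest other 0.0112), so over all genes a shared effect and chance from the shared libraries cannot be told apart. The covariance was 0.0175, 0.0141 and 0.0137 without Con replicate 1, 2 and 3, where fewer Con libraries raise it by construction, and with a different single Con library on each side, so that none was shared, it was -0.00106 to 0.000725. Over abundant genes the Pearson correlation was 0.748 against 0.498 simulated, and 10 of the 840 regroupings gave a covariance as high as the 0.0027 found (highest other 0.00285). Regroupings that keep Con as the shared group and mix STC1 with TGFb1 libraries can reach it too. That count therefore speaks to Con standing apart from the other libraries, and not to whether STC1 and TGFb1 share an effect. Different Con libraries on each side gave 0.0011 to 0.00266, which argues against chance from the shared libraries for those genes. A shared effect of both proteins on abundant genes may underlie this, as a hypothesis, with a difference in culture or handling of the Con group not tested.

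For each pair of groups there are 10 splits of the 6 libraries, too few for a share under 0.05. The numbers of called genes in the real split and the highest other were 6 and 8 for STC1 with Con, where 2 splits gave as many, 469 and 1 for TGFb1 with Con, 0 and 19 for TS with TGFb1, where all 10 did, 713 and 1 for TS with Con, and 35 and 4 for TS with STC1. With a real count of 0 the comparison of splits for TS with TGFb1 decides nothing, and the 19 genes came from the split that sets TS replicates 1 and 2 with TGFb1 replicate 1 against the others. The numbers of called lists were 12 and 7, 14 and 10, 6 and 4, 14 and 8, and 6 and 7, where for TS with STC1 2 splits gave as many and for the others 1. For the correlation of stanniocalcin-1 effects, computed here from group means, 60 of 100 combinations of splits were as high as the real 0.0102 (highest other 0.148), and for TGF-β1 effects 27 were as high as 0.0723 (highest other 0.144), so chance is not excluded for either. Over abundant genes the TGF-β1 effects, at 0.339, were matched in size by no other combination, the highest other being 0.318.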
